A study of Glycine max with 54 samples.

How the data were processed

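Gene expression was measured in leaves of the soybean line PI462312 on one-colour Affymetrix arrays. Per the labels, total RNA was extracted with TRIzol and Qiagen reagents from vegetative plants grown in soil mix, and was labelled with biotin. The leaves had been given a mock treatment, the virulent rust isolate Taiwan 80-2 or the avirulent isolate Hawaii 94-1, and were sampled at 6 times. The 3 treatments and 6 times made 18 groups of 3 replicates, and all 54 deposited columns were assigned from their labels.

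The deposited values are signal intensities on a linear scale. Per the submitters' processing notes they were made with MAS5; its version and parameters are not given in the sources used here. In the deposited table the mean of each column, without its lowest and highest values, lay between 500.145 and 500.2, so each array had been scaled to a common mean. The table holds 37763 probe sets, of which 122 are array controls and 37641 were taken as soybean; 48 of the latter measure ribosomal RNA.

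The deposited intensity was turned into log2(value + 16). Folds on this scale understate the change of genes with a low signal. The plan was to use the values as deposited if the median of each array lay within 0.25 log2 units of the overall median, and otherwise to apply quantile normalization. The deviations ranged from −0.44 to 0.16, so the log2 values were quantile normalized. A soybean probe set was tested if it lay above the 95th percentile of background probe sets on at least 3 arrays. Background was to come from probe sets of other organisms, but the table holds none that could be recognised; 20 unused control probe sets took their place, a change made after the table was seen and before any test. This left 36406 probe sets. The comparisons planned for probe sets of other organisms are not analysed here.

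All 54 arrays were fitted together with limma 3.58.1 in R 4.3.3, with a mean for each of the 18 groups and 36 residual degrees of freedom. The 18 contrasts were Hawaii 94-1 minus mock, Taiwan 80-2 minus mock and Hawaii 94-1 minus Taiwan 80-2 at each time. A probe set was called where limma's moderated test gave a Benjamini-Hochberg adjusted p under 0.05 within the contrast. Differences that change over time were tested with limma's moderated F-test of the 5 contrasts of each later time with 12 h, for each pair of treatments, and in the same way for mock leaves alone. The words rose and fell are used for called differences. Replicates enter as separate samples, as the labels link no numbers between groups. Whether same-numbered arrays deviated together from their group means was checked, with a bar of a correlation over 0.1 in every pair, and 4 of 18 comparisons met it.

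Gene names came from a table that pairs probe sets with symbols, updated through Entrez IDs with the RefSeq genes of Glycine_max_v4.0. Of 9047 probe sets in that table, 8677 had 1 symbol and 370 had several, and 8652 had an Entrez ID in the RefSeq genes; 28716 probe sets had no entry. A symbol that was not a placeholder was found for 1676 probe sets. No gene descriptions were used, so lists were filled by symbol alone and hold only part of each class. Gene lists, markers and reference genes were fixed as symbol patterns and measured on the probe set with the highest mean signal of each gene. Lists of 5 or more members were tested with limma's camera against the 975 genes with a symbol, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and contrasts. With an estimated correlation 0 camera calls held for the lists fixed beforehand, so a small preset p shows only that a list ranks high or low if its members vary independently. The lists for epidermis and vascular tissue had 0 members and were not analysed here.

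Genes were named by a rule. In each contrast the 3 largest rises and 2 largest falls were named among called probe sets with an absolute log2 difference of at least 1 and with all 3 values of one group above those of the other, on the probe set with the largest change. Chance alone separates 3 values from 3 in 10% of cases. For each list and kind of contrast, the 2 called members with the smallest adjusted p were named at the time with the most calls. For the F-tests, the 3 named genes with the smallest adjusted p were given. Gene functions are background knowledge and come from no file; where a symbol alone left the function unclear none is given.

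The design, the tests, the naming rule, the lists and the alternatives were chosen before the data were examined, except where a later choice is stated. The settings to be compared were the values as deposited without quantile normalization, each array centred on the median of tested probe sets, log2(value + 1), no filter, only the arrays of the groups compared, the replicate number as a block, limma with trend and robust settings, each array left out in turn, and camera with an estimated correlation. Settings added after the data were seen were the replicate number within each time as a block for those 4 comparisons, the GAPDH 3′ to middle difference as a covariate, the 72 h fit without 3 arrays, the F-tests without 12 h, and camera against all tested probe sets. The permutation tests of RNA quality and of replicate numbers, the draws that keep the replicate numbers and the recovery by signal level were also added then. The labels of the arrays were also exchanged between the groups compared, in all 10 splits of 3 against 3 arrays or in 100 draws for the F-tests. The code was tested on simulated data with 200 changed probe sets among 36406; the shares recovered are given for the comparison they simulated. The median share of soybean probe sets above background was 82.0% per array.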

Results

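Leaves of the soybean line PI462312, which carries the rust resistance gene Rpp3, were profiled after a mock treatment or after inoculation with an isolate of the Asian soybean rust fungus. Of the 2 isolates, Hawaii 94-1 is avirulent on this line and Taiwan 80-2 is virulent. Leaves given each of the 3 treatments were sampled at 12, 24, 72, 144, 216 and 288 h, which gave 18 groups of 3 arrays. Of 37641 soybean probe sets 36406 lay above background on enough arrays to be tested. The median soybean signal of an array ranged from 114 to 181, and 75.0 to 89.5% of the soybean probe sets of an array lay above its background limit. The precision is limited by the number of arrays, 3 per group. Nothing in the labels says that the replicates were separate plants or pools, so the p-values measure the spread between these samples, which may be technical. In 10 of the 18 groups the replicates held both a low and a high level of 2 APX2 probe sets, described below. This argues against 3 measurements of 1 RNA sample in those groups, and the other groups stay open.

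The 3′ bias of the GAPDH control transcript, which rises as RNA degrades, was lower in infected than in mock leaves over the time course. The log2 difference between the 3′ and the middle control probe sets of GAPDH, a glycolytic enzyme, was 0.49 ± 0.19 in mock leaves at 12 h (SD, n = 3). It was 0.31 ± 0.09 in Taiwan 80-2 leaves and 0.26 ± 0.12 in Hawaii 94-1 leaves at that time. At 72 h the values were 0.94 ± 0.13 in mock, 0.92 ± 0.13 in Taiwan 80-2 and 0.84 ± 0.25 in Hawaii 94-1 leaves, closer than their spread. The value reached 1.19 ± 0.14 in mock leaves at 216 h. Over the 6 times the 18 mock arrays lay 0.211 above the 36 infected arrays (2-sided permutation test within times, p = 0.00011). This test was added after the values were seen. The log2 difference between the 3′ and 5′ control probe sets of actin was not tested. It was highest in mock leaves at 12, 72, 144 and 216 h, but not at the other times. At 24 h it was 1.43 ± 0.15 in mock, 1.44 ± 0.11 in Taiwan 80-2 and 1.45 ± 0.34 in Hawaii 94-1 leaves. At 288 h it was 1.87 ± 0.45, 1.65 ± 0.41 and 2.01 ± 0.11 in that order. Replicates of a group correlated at 0.924 to 0.986 across probe sets, which are not independent replicates, and no 2 arrays were identical. Principal components 1 and 2 held 31.2% and 23% of the variance. Before normalization the medians of the Hawaii 94-1 arrays at 288 h lay at −0.32 ± 0.12 from the overall median on the log2 scale.

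The mock leaves were compared over time to show what changed without infection. Leaf age, time of day and RNA quality are not parted by the design: 12 h falls at another time of day than the multiples of 24 h, and the GAPDH difference of the mock arrays went from 0.49 at 12 h to 1.19 at 216 h. ELIP, an early light-induced protein of the thylakoid, had a mean log2 signal of 7.91 ± 0.62 at 12 h and 13.61 ± 0.18 at 24 h (SD, n = 3; adjusted p = 1.08e-21 over the time course). ZEP, zeaxanthin epoxidase of the xanthophyll cycle, went from 10.06 ± 0.30 to 13.24 ± 0.16 over the same interval (adjusted p = 4.56e-18). AG1 went from 12.83 ± 0.90 at 24 h to 5.22 ± 0.36 at 288 h (adjusted p = 6.83e-17). Limma's F-test called 20490 probe sets, 56.3% of those tested. From 12 to 24 h 10048 probe sets changed, from 24 to 72 h 6652 and from 72 to 144 h 3763. From 144 to 216 h limma called 0, with 1742 at an unadjusted p under 0.05, and from 216 to 288 h it called 14. Without replicate 3 of every group the count over the time course was 12456.

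**Figure D1:**
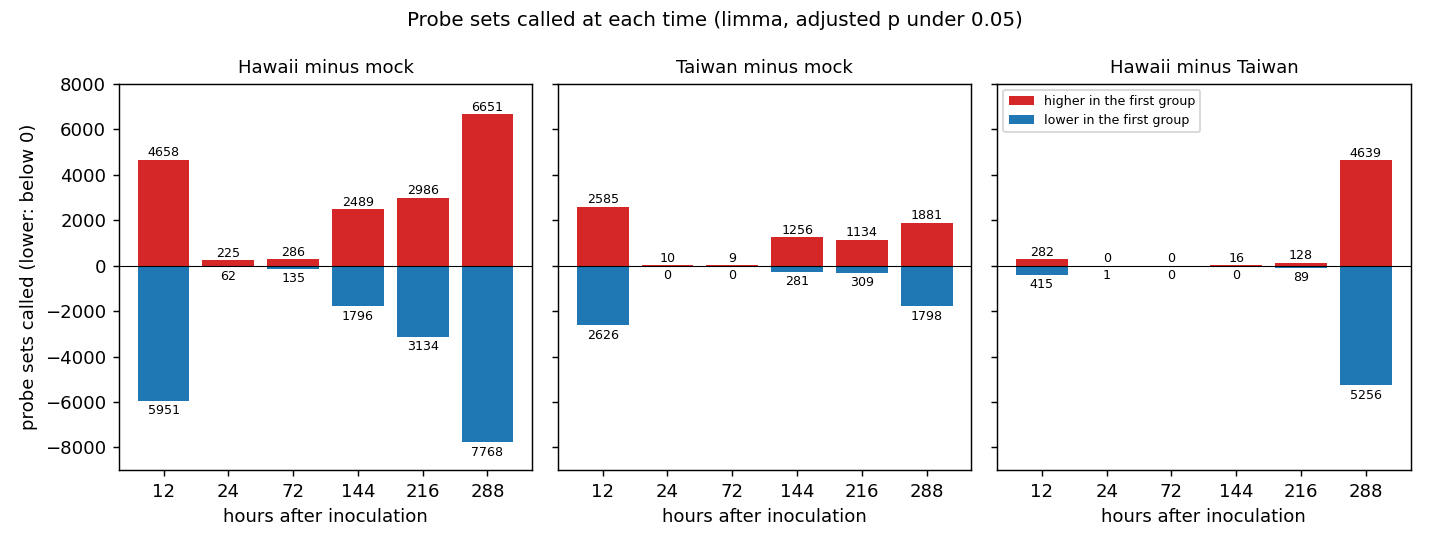
Number of probe sets called higher or lower (bars, adjusted p under 0.05) against time after inoculation in hours, in a panel for each of the 3 contrasts between treatments. Hawaii 94-1 minus mock had 10609 calls at 12 h, 287 at 24 h and 14419 at 288 h.

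At 12 h each isolate was compared with mock to show the early response of the leaf. G4DT, the prenyltransferase of glyceollin synthesis, rose by a log2 difference of 6.93 ± 0.75 in Hawaii 94-1 leaves (SE, n = 3 arrays per group; 122-fold; adjusted p = 1.34e-09) and by 5.77 ± 0.75 in Taiwan 80-2 leaves (adjusted p = 2.03e-07). Its mean log2 signal was 6.46 ± 1.12 in mock, 12.23 ± 1.05 in Taiwan 80-2 and 13.39 ± 0.43 in Hawaii 94-1 leaves (SD). CHS1, chalcone synthase, rose by 6.81 ± 0.57 and 6.70 ± 0.57 in Hawaii 94-1 and Taiwan 80-2 leaves (adjusted p = 2.89e-12 and 1.05e-11), and another CHS1 probe set, the brightest, rose by 4.74 ± 0.37 in Taiwan 80-2 leaves. IFR, isoflavone reductase, rose by 6.44 ± 0.79 and 5.99 ± 0.79, and HIDH, 2-hydroxyisoflavanone dehydratase, by 4.26 ± 0.34 in Taiwan 80-2 leaves. Among called probe sets with a gene symbol and no overlap between the groups, the largest falls in Hawaii 94-1 leaves were of MYB173, listed here with the clock genes, with −3.41 ± 0.38, and of DXR2, an enzyme of plastid isoprenoid synthesis, with −3.14 ± 0.25. AG1 fell by 3.72 ± 0.55 in Taiwan 80-2 leaves, and PAP25, a purple acid phosphatase, fell by 2.93 ± 0.54. Limma called 10609 probe sets in Hawaii 94-1 against mock (4658 higher, 5951 lower) and 5211 in Taiwan 80-2 against mock (2585 higher, 2626 lower), and 3292 in the latter without Taiwan replicate 2. With only the arrays compared the counts were 6478 (3314 higher, 3164 lower) and 2208 (1679 higher, 529 lower). The median log2 difference of all probe sets was −0.10 for Hawaii 94-1, −0.12 with the values as deposited, and −0.15 for Taiwan 80-2 with each array centred on its median.

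Phytoalexin and defence genes were among those that rose at 12 h, when 215 of 975 named genes rose in Hawaii 94-1 leaves and 135 in Taiwan 80-2 leaves. Of 20 isoflavonoid and pterocarpan genes, 14 rose in Hawaii 94-1 leaves (14 adjusted over the list alone), with a median log2 difference of 4.11, and 14 rose in Taiwan 80-2 leaves (14 adjusted over the list alone), with a median of 3.68. The camera test placed them above the other named genes (adjusted p = 3.34e-07 and 2.78e-09), but with adjusted p = 0.261 and 0.241 with an estimated correlation. Of 8 phenylpropanoid and lignin genes, 7 rose in each (7 and 7 adjusted over the list alone; camera adjusted p = 1.78e-05 and 2.57e-07, and 0.241 and 0.201 with an estimated correlation). Among them the 4-coumarate:CoA ligases 4CL2 and 4CL4 rose by 4.71 ± 0.37 and 4.65 ± 0.37 in Hawaii 94-1 leaves and by 3.88 ± 0.37 and 3.96 ± 0.37 in Taiwan 80-2 leaves. Of 52 WRKY transcription factors, 24 rose and 2 fell in Hawaii 94-1 leaves (26 and 3 adjusted over the list alone) and 18 rose in Taiwan 80-2 leaves (21 rose and 2 fell adjusted over the list alone). Their camera adjusted p was 0.00088 and 0.00089, and 0.433 and 0.433 with an estimated correlation. WRKY46 and WRKY56 rose by 3.75 ± 0.38 and 3.48 ± 0.36 in Taiwan 80-2 leaves. Of 9 resistance signalling genes 7 rose in each (7 and 7 adjusted over the list alone; camera adjusted p = 0.00151 and 0.000447, and 0.358 and 0.311 with an estimated correlation). They included the kinase MPK4B (2.40 ± 0.26 and 2.06 ± 0.26), the lipase-like regulator PAD4 (2.12 ± 0.31 in Taiwan 80-2 leaves) and the chaperone HSP90-1 (2.00 ± 0.26 and 1.61 ± 0.26).

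Some detoxification and stress genes rose at 12 h. Of 24 glutathione S-transferases, 11 rose and 3 fell in Hawaii 94-1 leaves (11 and 3 adjusted over the list alone) and 10 rose and 3 fell in Taiwan 80-2 leaves (12 and 3 adjusted over the list alone; camera adjusted p = 0.0256, and 0.461 with an estimated correlation). GSTU13 rose by 5.74 ± 0.51 and 5.46 ± 0.51, GSTU58 by 4.86 ± 0.51 in Hawaii 94-1 leaves and GSTU27 by 2.98 ± 0.40 in Taiwan 80-2 leaves. Of 7 pathogenesis-related proteins, 5 rose in Hawaii 94-1 leaves (6 adjusted over the list alone; camera adjusted p = 0.00789, and 0.453 with an estimated correlation) and 3 in Taiwan 80-2 leaves (3 adjusted over the list alone). Of 16 heat shock proteins and factors, 9 rose and 2 fell in Hawaii 94-1 leaves (9 and 2 adjusted over the list alone) and 6 rose and 1 fell in Taiwan 80-2 leaves (8 and 2 adjusted over the list alone), HSF-15 by 1.71 ± 0.22 and 1.41 ± 0.22. ACS1, which makes the ethylene precursor, rose by 3.23 ± 0.36 and 2.72 ± 0.36. Of the 4 ethylene genes 3 rose in Hawaii 94-1 leaves and 2 in Taiwan 80-2 leaves (3 rose and 1 fell in each adjusted over the list alone), among them the receptor ETR2 (1.74 ± 0.34 in Hawaii 94-1 leaves) and ACS (1.22 ± 0.32 in Taiwan 80-2 leaves). Of 4 ERF genes, 2 and 1 rose (3 and 2 adjusted over the list alone), and ERF6 rose by 1.12 ± 0.34 in Taiwan 80-2 leaves. Of 15 NAC genes, 5 and 4 rose (5 and 6 adjusted over the list alone). Of 10 sugar transport genes, 1 rose and 2 fell in each (1 and 2 adjusted over the list alone). The importer STP1 rose by 2.28 ± 0.26 and 1.93 ± 0.26, and the exporter SWEET34 fell (−2.25 ± 0.39 and −1.43 ± 0.39). SGR1 and SARK, senescence genes, rose by 1.23 ± 0.32 and 0.76 ± 0.26 in Taiwan 80-2 leaves, and PRX4, a peroxidase, by 3.97 ± 1.11. SARK was called under neither other scaling.

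Clock and carbon fixation genes were among those that fell at 12 h, when 169 of 975 named genes fell in Hawaii 94-1 leaves and 98 in Taiwan 80-2 leaves. Of 8 clock genes, 5 fell in Hawaii 94-1 leaves (5 adjusted over the list alone) and 4 in Taiwan 80-2 leaves (7 adjusted over the list alone), with camera adjusted p = 0.00197 and 0.00797, and 0.311 and 0.384 with an estimated correlation. MYB173 fell by 2.34 ± 0.38 in Taiwan 80-2 leaves and LHY fell by 1.03 ± 0.27. Of 5 Calvin cycle genes, 4 fell in Hawaii 94-1 leaves (5 adjusted over the list alone) and 3 in Taiwan 80-2 leaves (4 adjusted over the list alone), with camera adjusted p = 0.00293 and 0.0166, and 0.358 and 0.444 with an estimated correlation. The rubisco activases RCA14 and RCAALPHA fell in Taiwan 80-2 leaves (−0.86 ± 0.14 and −0.97 ± 0.19). CHLH, a magnesium chelatase subunit and 1 of 2 chlorophyll synthesis genes, fell in each (−1.83 ± 0.31 and −1.86 ± 0.31), and the other was not called. Of 4 light reaction genes 3 fell in Hawaii 94-1 leaves and 2 in Taiwan 80-2 leaves (3 and 2 adjusted over the list alone), ATPC of the ATP synthase and CAB3 of the light-harvesting complex with −0.81 ± 0.22 and −0.85 ± 0.24 in the latter. KR1, 1 of 2 resistance proteins of the NBS-LRR type, fell in each (−1.72 ± 0.33 and −1.48 ± 0.33). SERK1, a receptor-like kinase, fell by 0.65 ± 0.23 in Taiwan 80-2 leaves, but was not called with the values as deposited. Of 5 cell wall genes 1 fell in Hawaii 94-1 leaves and 3 in Taiwan 80-2 leaves (3 adjusted over the list alone), the expansins EXP4 and EXP2 with −2.80 ± 0.66 and −1.64 ± 0.55 in the latter.

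The isolates were compared with each other at 12 h to ask whether the avirulent isolate drew another early response. PR1-1, a pathogenesis-related protein, was higher in Hawaii 94-1 than in Taiwan 80-2 leaves by 2.63 ± 0.71 (SE, n = 3 per group; adjusted p = 0.0399). AG1 was higher by 2.51 ± 0.55 and ALDH3H1, an aldehyde dehydrogenase, by 2.49 ± 0.48 (adjusted p = 0.00937 and 0.00337). AG1 had a mean log2 signal of 10.28 ± 0.43 in mock, 6.56 ± 0.27 in Taiwan 80-2 and 9.06 ± 0.59 in Hawaii 94-1 leaves (SD). VPE2, a vacuolar processing enzyme, was lower with a difference of −2.08 ± 0.46 and PEPC17, a phosphoenolpyruvate carboxylase, with −1.49 ± 0.40 (adjusted p = 0.011 and 0.0372); neither was called with the arrays centred. Of the pathogenesis-related proteins 1 was higher (3 adjusted over the list alone; camera adjusted p = 0.00111, and 0.367 with an estimated correlation). Of the Calvin cycle genes 2 were lower (2 adjusted over the list alone; camera adjusted p = 0.00274, and 0.358 with an estimated correlation), and limma called 0 of them under both other scalings. The clock genes had a camera adjusted p of 0.0134, and 0.433 with an estimated correlation. Limma called 697 probe sets, 282 higher and 415 lower; 40.5% were higher, against 29.5% with the values as deposited (184 of 623) and 65.4% with each array centred on its median (261 of 399). These calls rest on the spread shared by all 54 arrays. With only the 6 arrays compared limma called 0, with 4588 at an unadjusted p under 0.05, and none of the 5 genes named here was called. The count was 316 without Taiwan replicate 1, 256 without Taiwan replicate 3 and 304 without Hawaii replicate 2.

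At 24 h the comparisons asked what was left of the early response. PTS-L4 rose by 3.38 ± 0.51 in Hawaii 94-1 leaves (SE, n = 3 per group; adjusted p = 0.000376) and by 2.77 ± 0.51 in Taiwan 80-2 leaves (adjusted p = 0.0246), where it was the only named gene called. In Hawaii 94-1 leaves the peroxidase PRX4 rose by 4.45 ± 1.00 (adjusted p = 0.0166). The pathogenesis-related gene PR-10 rose there by 3.91 ± 0.86 (adjusted p = 0.0151). GASA6, a gibberellin-regulated peptide, fell by 2.43 ± 0.51 and HSP90A1, a chaperone, fell by 2.40 ± 0.61 (adjusted p = 0.00957 and 0.0474), and HSP90A1 was not called with the arrays centred. Of these 5 genes in Hawaii 94-1 leaves, PTS-L4 alone was called with only the arrays compared. In Taiwan 80-2 leaves PTS-L4 was not called under that setting, in which limma called 0 probe sets, with 2107 at an unadjusted p under 0.05. Of the isoflavonoid genes 5 rose in Hawaii 94-1 leaves (10 adjusted over the list alone; camera adjusted p = 2.3e-06, and 0.311 with an estimated correlation), and of the pathogenesis-related proteins 2 (5 adjusted over the list alone; camera adjusted p = 1.83e-05, and 0.241 with an estimated correlation). In Taiwan 80-2 leaves no member of these lists passed over all probe sets (3 and 2 adjusted over the list alone; camera adjusted p = 0.000398 and 0.000447, and 0.433 and 0.35 with an estimated correlation). Between the isolates camera placed the jasmonate list lower in Hawaii 94-1 leaves (adjusted p = 1.78e-05, and 0.241 with an estimated correlation), the protease inhibitors lower (0.0118, and 0.241) and the isoflavonoid and pathogenesis-related lists higher (0.00217 and 0.0106, and 0.476 and 0.461), all with no called member. Against mock the receptor-like kinases and the protease inhibitors were lower in Hawaii 94-1 leaves (camera adjusted p = 0.0241 and 0.0259, and 0.433 and 0.242 with an estimated correlation).

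Limma called 287 probe sets at 24 h for Hawaii 94-1 against mock (225 higher, 62 lower), 10 for Taiwan 80-2 against mock, all higher, and 1 for Hawaii 94-1 against Taiwan 80-2. The last was lower by a log2 difference of −2.42 ± 0.38 (adjusted p = 0.00422) and has no gene name in the tables used here. The Hawaii 94-1 count was 50 without mock replicate 1, 475 without mock replicate 2, 173 without Hawaii replicate 1, and 88 without Hawaii replicate 2 or Hawaii replicate 3. The Taiwan 80-2 count was 6, 108 and 2 without mock replicates 1, 2 and 3, and 0, 1 and 3 without Taiwan replicates 1, 2 and 3, and limma called 1703 at an unadjusted p under 0.05. The single call between the isolates became 0 without Taiwan replicate 1, Hawaii replicate 1 or Hawaii replicate 3 and 3 without Taiwan replicate 3, with 929 at an unadjusted p under 0.05. Same-numbered arrays of these groups deviated together. For them limma called 4 probe sets with the replicate number as a block and 5 with the number within each time as a block, all lower. In data simulated for Taiwan 80-2 against mock at 24 h, limma recovered 95.5% of 4-fold and 26.9% of 2-fold changes. No simulated array stood apart from its group, so these shares may be too high for the real arrays.

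At 72 h some defence genes rose in Hawaii 94-1 leaves. PR-10 rose by 4.86 ± 0.86 (SE, n = 3 per group; adjusted p = 0.00147), PT01 by 4.67 ± 0.62 (adjusted p = 2.5e-05). The glutathione S-transferase GSTU42 rose by 4.33 ± 0.67 (adjusted p = 0.000258). TSB, the beta subunit of tryptophan synthase, fell by 2.84 ± 0.66 (adjusted p = 0.0196), and the wall genes XTH1, a xyloglucan endotransglucosylase, and EXP1, an expansin, fell with differences of −2.32 ± 0.39 and −1.24 ± 0.33 (adjusted p = 0.000637 and 0.0492). EXP1 was called under neither other scaling. PR-10, TSB, XTH1 and EXP1 were not called with only the arrays compared, where limma called 42 probe sets, all higher. Of the pathogenesis-related proteins 4 rose (6 adjusted over the list alone; camera adjusted p = 2.57e-07, and 0.201 with an estimated correlation), of the isoflavonoid genes 3 (6 rose and 1 fell adjusted over the list alone; 0.00111, and 0.461), of the WRKY factors 3 (15 adjusted over the list alone; 0.000904, and 0.433) and of the glutathione S-transferases 3 (6 adjusted over the list alone; 0.00931, and 0.433). Of the cell wall genes 2 fell (2 adjusted over the list alone, and 1 over all probe sets under each other scaling; camera adjusted p = 0.0134, and 0.241 with an estimated correlation).

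In Taiwan 80-2 leaves at 72 h no named gene was called. Camera placed the pathogenesis-related proteins (adjusted p = 3.34e-07, and 0.201 with an estimated correlation), the WRKY factors (4.74e-05, and 0.358), the isoflavonoid genes (0.000385, and 0.433), the glutathione S-transferases (0.00416, and 0.359) and the resistance signalling genes (0.0216, and 0.472) above the other named genes. Between the isolates the pathogenesis-related list was higher in Hawaii 94-1 leaves (camera adjusted p = 0.00293, and 0.433 with an estimated correlation), and the cell wall and jasmonate lists were lower (0.00797 and 0.0315, and 0.241 and 0.532). Limma called 421 probe sets for Hawaii 94-1 against mock (286 higher, 135 lower), 9 for Taiwan 80-2 against mock, all higher, and 0 for Hawaii 94-1 against Taiwan 80-2, with 1347 and 2872 at an unadjusted p under 0.05 in the last 2 contrasts. The first count was 1326, 168 and 72 without mock replicates 1, 2 and 3, and 770, 160 and 200 without Hawaii replicates 1, 2 and 3. The second was 126 without mock replicate 1, 2 without mock replicate 3, 0 without Taiwan replicate 1 and 4 without Taiwan replicate 2. The third was 67 without Taiwan replicate 3 and 317 without Hawaii replicate 1.

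At 144 h pathogenesis-related genes were among the largest rises of named genes with both isolates. OLPa, an osmotin-like protein, rose by 6.38 ± 0.59 in Hawaii 94-1 leaves (SE, n = 3 per group; adjusted p = 3e-10) and by 5.95 ± 0.59 in Taiwan 80-2 leaves (adjusted p = 7.36e-09), and by 5.25 ± 0.62 in the latter on its brightest probe set. PR-10 rose by 5.22 ± 0.97 in Hawaii 94-1 leaves (adjusted p = 0.000169) and by 5.18 on the same probe set in Taiwan 80-2 leaves (adjusted p = 5e-04). Another PR-10 probe set rose by 5.34 ± 0.86 in the latter (adjusted p = 5.58e-05). GSTU42 rose by 5.75 ± 0.67 in Hawaii 94-1 leaves (adjusted p = 4.48e-08) and the chitinase CHIA1 by 5.41 ± 0.56 in Taiwan 80-2 leaves (adjusted p = 1.8e-08). In Hawaii 94-1 leaves the lipoxygenase LOX7 fell by 3.07 ± 0.76 and GA2OX6, which inactivates gibberellins, fell by 2.91 ± 0.95 (adjusted p = 0.00484 and 0.0374). IQD40, a calmodulin-binding protein, fell by 1.88 ± 0.40 in Taiwan 80-2 leaves and the cysteine protease CYSP2 fell by 1.85 ± 0.55 (adjusted p = 0.00255 and 0.044), and CYSP2 was not called with the arrays centred. Of 4 ribosomal protein genes, 1 rose in Hawaii 94-1 leaves and 3 in Taiwan 80-2 leaves (4 in each adjusted over the list alone), RPL2 by 0.87 ± 0.26 and 1.02 ± 0.26 and RPL37 by 1.07 ± 0.27 in the latter. H4, the only member of the cell cycle and histone list, rose by 2.05 ± 0.54 in Taiwan 80-2 leaves. In Hawaii 94-1 leaves it rose at each time from 12 to 216 h, by 1.98 ± 0.54 at 12 h, but was not called at 24 and 216 h with the values as deposited, or at 216 h with the arrays centred. Its probe set shares an array design cluster with PR-10 probe sets, so whether it measures a histone is not established.

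Of the pathogenesis-related proteins 6 rose at 144 h in Hawaii 94-1 leaves and 6 in Taiwan 80-2 leaves (7 and 7 adjusted over the list alone), with medians of 4.12 and 3.67 (camera adjusted p = 3.34e-07 and 2.78e-09, and 0.201 and 0.201 with an estimated correlation). Of the isoflavonoid genes 14 and 10 rose (16 and 13 adjusted over the list alone), with medians of 2.38 and 1.99 (2.57e-07 and 2.59e-07, and 0.242 and 0.242). Of the WRKY factors 20 rose and 2 fell in Hawaii 94-1 leaves (28 and 3 adjusted over the list alone) and 12 rose in Taiwan 80-2 leaves (20 rose and 1 fell adjusted over the list alone; 1.17e-05 and 0.000853, and 0.311 and 0.433). Phenylpropanoid genes rose in number 5 and 2 (7 rose and 1 fell, and 3 rose, adjusted over the list alone; 0.00111 in Hawaii 94-1 leaves, and 0.359), glutathione S-transferases 8 and 4 (11 rose and 1 fell, and 10 rose, adjusted over the list alone; 0.0304 and 0.0259, and 0.469 and 0.461) and resistance signalling genes 5 and 2 (6 and 3 adjusted over the list alone; 0.0299 in Hawaii 94-1 leaves, and 0.497). Of 11 jasmonate and oxylipin genes, 4 fell in Hawaii 94-1 leaves (4 adjusted over the list alone; camera adjusted p = 0.0137, and 0.471 with an estimated correlation), and 2 of 5 senescence genes fell (2 adjusted over the list alone).

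Limma called 4285 probe sets at 144 h for Hawaii 94-1 against mock (2489 higher, 1796 lower), 1537 for Taiwan 80-2 against mock (1256 higher, 281 lower) and 16 for Hawaii 94-1 against Taiwan 80-2, all higher and none with a gene symbol that is not a placeholder. Between the isolates camera placed the phenylpropanoid, WRKY, isoflavonoid, NAC and resistance signalling lists higher in Hawaii 94-1 leaves (adjusted p = 4.63e-05, 5.04e-05, 0.00858, 0.0134 and 0.0113, and 0.242, 0.358, 0.55, 0.521 and 0.453 with an estimated correlation). It placed the jasmonate list lower (0.00433, and 0.433). With only the arrays compared the first 2 counts were 2843 (1854 higher, 989 lower) and 641 (620 higher, 21 lower). The first count was 2729 without mock replicate 1, 2186 without Hawaii replicate 1 and 2698 without Hawaii replicate 3. The second was 744 and 876 without mock replicates 1 and 3 and 473 without Taiwan replicate 1. The third was 37, 0 and 2 without Taiwan replicates 1, 2 and 3 and 0 without Hawaii replicate 1 or Hawaii replicate 3, with 2073 at an unadjusted p under 0.05. With the arrays centred the median of all probe sets for Hawaii 94-1 against mock was −0.11.

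**Figure D2:**
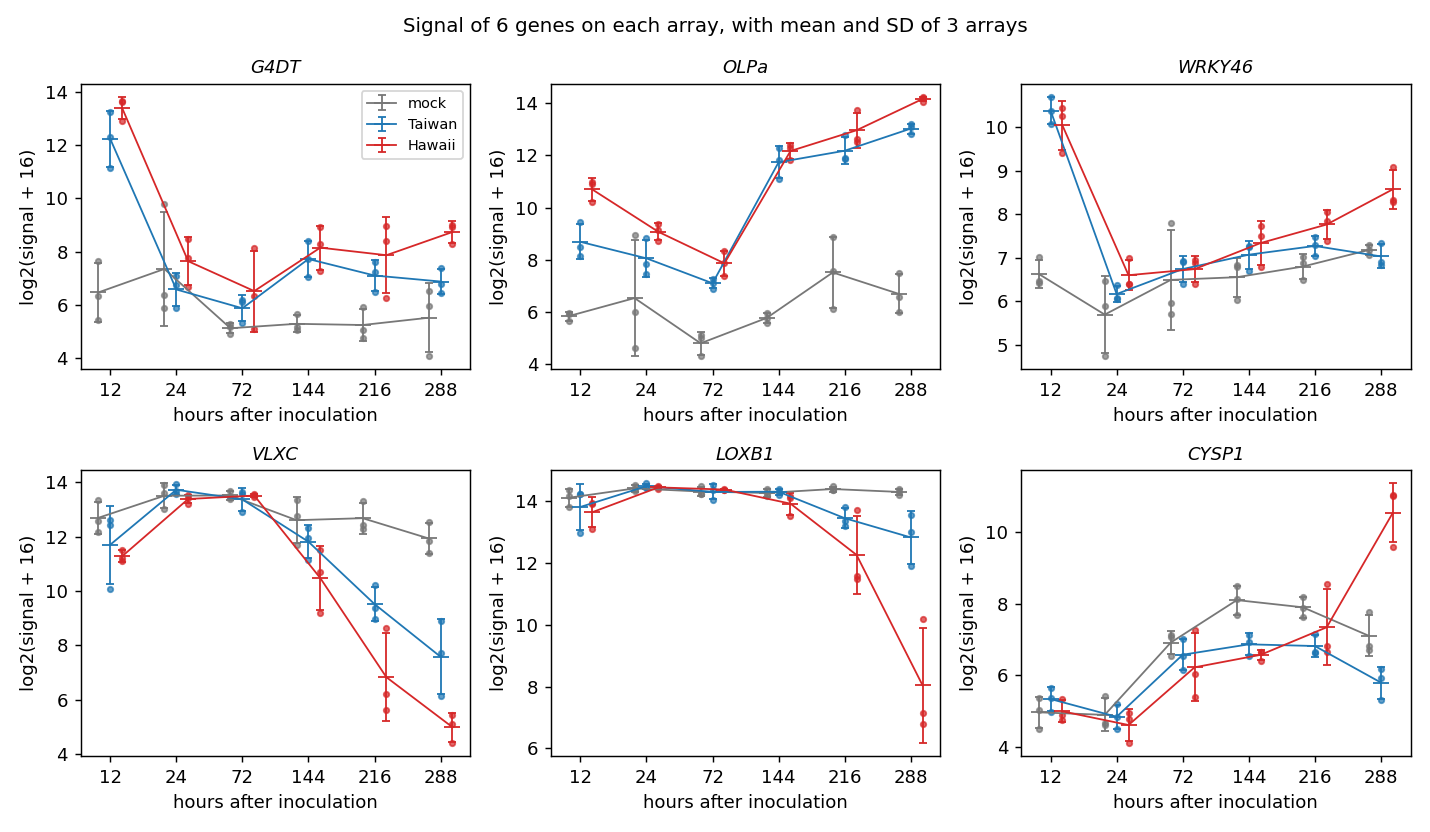
Log2(signal + 16) of G4DT, OLPa, WRKY46, VLXC, LOXB1 and CYSP1, on 1 probe set per gene, against hours after inoculation; points are arrays, and lines and bars are the mean and SD of 3 arrays per treatment. G4DT in Hawaii 94-1 leaves was at 13.39 at 12 h against 6.46 in mock leaves, and CYSP1 in Hawaii 94-1 leaves was at 10.54 at 288 h against 7.11 in mock leaves.

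At 216 h some defence genes were higher than in mock leaves and some lipoxygenase genes were lower. OLPa rose by 5.62 ± 0.67 in Hawaii 94-1 leaves and by 4.87 ± 0.67 in Taiwan 80-2 leaves (SE, n = 3 per group; adjusted p = 7.52e-08 and 3.95e-06). In Hawaii 94-1 leaves ICL1, isocitrate lyase of the glyoxylate cycle, rose by 5.44 ± 1.2 and PRX4 by 5.28 ± 1.11 (adjusted p = 0.00103 and 0.000615). In Taiwan 80-2 leaves GSTU42 rose by 4.47 ± 0.67 and PT01 by 4.17 ± 0.62 (adjusted p = 1.76e-05 and 1.57e-05). VLXC, a vegetative lipoxygenase, fell in each (−5.86 ± 0.61 and −3.16 ± 0.61; adjusted p = 6.4e-09 and 0.000727). NES fell by 4.75 ± 0.97 in Hawaii 94-1 leaves (adjusted p = 0.000393). LOX7 fell by 2.86 ± 0.86 in Taiwan 80-2 leaves (adjusted p = 0.0469). All 7 pathogenesis-related proteins rose in Hawaii 94-1 leaves (7 adjusted over the list alone), among them PR1-7 by 3.94 ± 0.46 and CHIA1 by 4.48 ± 0.56, and 5 rose in Taiwan 80-2 leaves (6 adjusted over the list alone), with camera adjusted p = 2.3e-06 and 3.34e-07, and 0.241 and 0.201 with an estimated correlation. Of the jasmonate genes 6 fell in Hawaii 94-1 leaves (1 rose and 7 fell adjusted over the list alone) and 3 in Taiwan 80-2 leaves (1 rose and 4 fell adjusted over the list alone), with camera adjusted p = 0.00131 and 0.00293, and 0.372 and 0.433 with an estimated correlation. In Hawaii 94-1 leaves the allene oxide cyclase AOC6 fell by 3.47 ± 0.51 and LOX7 fell by 4.43 ± 0.76, on another probe set than in Taiwan 80-2 leaves. Of 7 protease inhibitors 1 rose there and 2 fell (1 and 2 adjusted over the list alone), BBI-1, a Bowman-Birk inhibitor, by 5.17 ± 0.71 and KTI-3, a trypsin inhibitor, by −2.85 ± 0.75. Of 4 peroxidases 1 rose and 2 fell (1 and 2 adjusted over the list alone), PRX2 by −1.98 ± 0.53.

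Of the isoflavonoid genes 14 rose at 216 h in Hawaii 94-1 leaves and 10 in Taiwan 80-2 leaves (16 rose and 1 fell, and 14 rose, adjusted over the list alone), with camera adjusted p = 2.3e-06 and 3.5e-08, and 0.311 and 0.241 with an estimated correlation. Phenylpropanoid genes rose in number 7 and 5 (7 rose, and 6 rose and 1 fell, adjusted over the list alone; 0.000434 and 0.000434, and 0.317 and 0.317). Of the WRKY factors 19 rose and 1 fell, and 11 rose (23 and 3, and 20 and 1, adjusted over the list alone; 0.000434 and 5.38e-05, and 0.433 and 0.358). Of the glutathione S-transferases 12 rose and 1 fell, and 5 rose (12 and 1, and 10 rose, adjusted over the list alone; 0.0279 and 0.0108, and 0.461 and 0.433). Of the NAC factors 7 and 1 rose (8 in Hawaii 94-1 leaves adjusted over the list alone; 0.00917, and 0.485), and of the clock genes 3 fell in Hawaii 94-1 leaves (4 adjusted over the list alone; 0.0259, and 0.454). Limma called 6120 probe sets for Hawaii 94-1 against mock (2986 higher, 3134 lower; 3842 without Hawaii replicate 2) and 1443 for Taiwan 80-2 against mock (1134 higher, 309 lower). The latter count was 873 and 822 without mock replicates 1 and 3 and 596 without Taiwan replicate 1. It was 681 (583 higher, 98 lower) with only the arrays compared.

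Between the isolates at 216 h, PR1-1 was higher in Hawaii 94-1 leaves by 3.23 ± 0.71 (SE, n = 3 per group; adjusted p = 0.0166), BCH3 by 2.48 ± 0.36 (adjusted p = 7.72e-05) and the transcription factor NAC3 by 2.03 ± 0.38 (adjusted p = 0.00284), on a probe set other than its brightest. VLXC had a difference of −2.69 ± 0.61 and SALI5-4A, 1 of whose 3 probe sets was called, of −2.50 ± 0.62 (adjusted p = 0.0219 and 0.0426); SALI5-4A was not called with the arrays centred. Of the vegetative storage genes 1 was lower (2 adjusted over the list alone), and the 1 light reaction gene called was not called under both other scalings. Camera placed the phenylpropanoid, pathogenesis-related and NAC lists higher (adjusted p = 0.0445, 0.0416 and 0.0137, and 0.55, 0.555 and 0.524 with an estimated correlation) and the jasmonate and clock lists lower (0.0352 and 0.0373, and 0.547 and 0.469). Limma called 217 probe sets (128 higher, 89 lower), and 1 with only the 6 arrays compared, so these calls rest on the spread shared by all 54 arrays. None of the 5 genes named here was called with only the arrays compared. The count was 137 and 73 without Taiwan replicates 2 and 3, and 132 and 39 without Hawaii replicates 1 and 2.

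At 288 h 265 of 975 named genes rose and 246 fell in Hawaii 94-1 leaves against mock. OLPa rose by 7.45 ± 0.59 in Hawaii 94-1 leaves (SE, n = 3 per group; 175-fold; adjusted p = 3.5e-13) and by 6.32 on the same probe set in Taiwan 80-2 leaves (adjusted p = 3.72e-10), where another OLPa probe set rose by 6.54 ± 0.67 (adjusted p = 3.77e-09). On its brightest probe set its mean log2 signal was 7.55 ± 0.66 in mock, 13.10 ± 0.22 in Taiwan 80-2 and 14.07 ± 0.13 in Hawaii 94-1 leaves (SD). In Hawaii 94-1 leaves PRX4 rose by 6.90 ± 1.11 and ICL1 by 6.78 ± 0.73 (adjusted p = 2.64e-06 and 6.28e-10), and the ammonium transporter AMT1.3 fell by 6.71 ± 0.68 (adjusted p = 1.69e-10). VLXC fell by 6.95 ± 0.61 in Hawaii 94-1 leaves and fell by 4.36 ± 0.61 in Taiwan 80-2 leaves (adjusted p = 5.53e-12 and 2.52e-06), and VLXB, another vegetative lipoxygenase, fell in each (−5.27 ± 0.44 and −1.63 ± 0.44). PR-10 rose by 5.37 ± 0.86 in Taiwan 80-2 leaves (adjusted p = 2.59e-05). APX2, ascorbate peroxidase, was called in both directions in Taiwan 80-2 leaves, with differences of 7.23 ± 2.12 and −7.04 ± 2.26 on 2 of its probe sets (adjusted p = 0.0212 and 0.0381). At 288 h all arrays of a group were at the same level, but in 10 of the 18 groups, all at other times, these probe sets were low on some arrays and high on others. Limma called 14419 probe sets for Hawaii 94-1 against mock (6651 higher, 7768 lower) and 3679 for Taiwan 80-2 against mock (1881 higher, 1798 lower; 2317 without Taiwan replicate 2). The median of all probe sets for Hawaii 94-1 against mock was −0.04, and −0.19 with the values as deposited and 0.12 with the arrays centred. Of the calls 46.1% were higher, and 56.8% with the arrays centred (8348 of 14700).

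Photosynthesis genes were among those that fell at 288 h in Hawaii 94-1 leaves, and senescence genes among those that rose. All 4 light reaction genes fell, ATPC with −2.44 ± 0.22 and PSAD of photosystem I with −1.81 ± 0.19, and all 5 Calvin cycle genes fell (5 adjusted over the list alone, 3 over all probe sets with the arrays centred; camera adjusted p = 0.0183, and 0.452 with an estimated correlation), FBP, fructose-1,6-bisphosphatase, with −3.19 ± 0.26 and RCABETA with −2.29 ± 0.48. Of the clock genes 6 fell (6 adjusted over the list alone; 0.0216, and 0.444), COL2A with −3.96 ± 0.44 and MYB173 with −2.55 ± 0.38. All 5 senescence genes rose (5 adjusted over the list alone; 0.0334, and 0.433), the cysteine proteases CYSP1 and CYSP2 by 3.44 ± 0.41 and 4.07 ± 0.55. Of the jasmonate genes 6 fell in each of the Hawaii 94-1 and Taiwan 80-2 leaves (6 and 6 adjusted over the list alone; 0.0118 and 0.0118, and 0.461 and 0.461), the allene oxide cyclases AOC3 and AOC6 with −1.94 ± 0.35 and −2.30 ± 0.51 in the latter. Of the NAC factors 10 and 5 rose (10 and 5 adjusted over the list alone; 0.00497 and 0.00858, and 0.461 and 0.483), NAC51 by 2.94 ± 0.35 and NAC4 by 3.47 ± 0.43 in Hawaii 94-1 leaves, and NAC23 by 3.07 ± 0.56 and NAC4 by 1.60 ± 0.43 in Taiwan 80-2 leaves. Of the receptor-like kinases 3 rose in Hawaii 94-1 leaves (3 adjusted over the list alone), RLK3 by 3.65 ± 0.39 and RLK2 by 1.82 ± 0.24, and ERF5 and ERF3 rose by 3.38 ± 0.42 and 0.41 ± 0.14. BBI-1 rose by 4.24 ± 0.71 in Taiwan 80-2 leaves and KTI-3 fell by 2.90 ± 0.75.

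Defence lists at 288 h held called members in both infections. Of the isoflavonoid genes 14 rose and 1 fell in Hawaii 94-1 leaves (14 and 1 adjusted over the list alone) and 12 rose in Taiwan 80-2 leaves (14 adjusted over the list alone), with camera adjusted p = 0.00203 and 1.55e-07, and 0.474 and 0.241 with an estimated correlation. The chalcone reductases CHR4 and CHR3 rose by 2.84 ± 0.28 and 2.75 ± 0.34 in Hawaii 94-1 leaves. Of the pathogenesis-related proteins 6 and 5 rose (7 and 6 adjusted over the list alone; 0.00102 and 1.04e-05, and 0.359 and 0.241). Of the WRKY factors 29 rose and 6 fell (30 and 3 with the arrays centred), and 17 rose and 1 fell (29 and 6, and 21 and 2, adjusted over the list alone; 0.00497 and 0.0017, and 0.485 and 0.461), WRKY62 by 3.31 ± 0.37 and WRKY9 by 2.45 ± 0.28 in Hawaii 94-1 leaves. The WRKY fall in Taiwan 80-2 leaves was called under neither other scaling. Phenylpropanoid genes numbered 3 risen and 1 fallen, and 5 risen (3 and 1, and 6, adjusted over the list alone; 0.00497 in Taiwan 80-2 leaves, and 0.433), and glutathione S-transferases 9 risen and 4 fallen, and 10 risen and 2 fallen (11 and 5, and 10 and 2, adjusted over the list alone; 0.0248 in Taiwan 80-2 leaves, and 0.461).

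**Figure D3:**
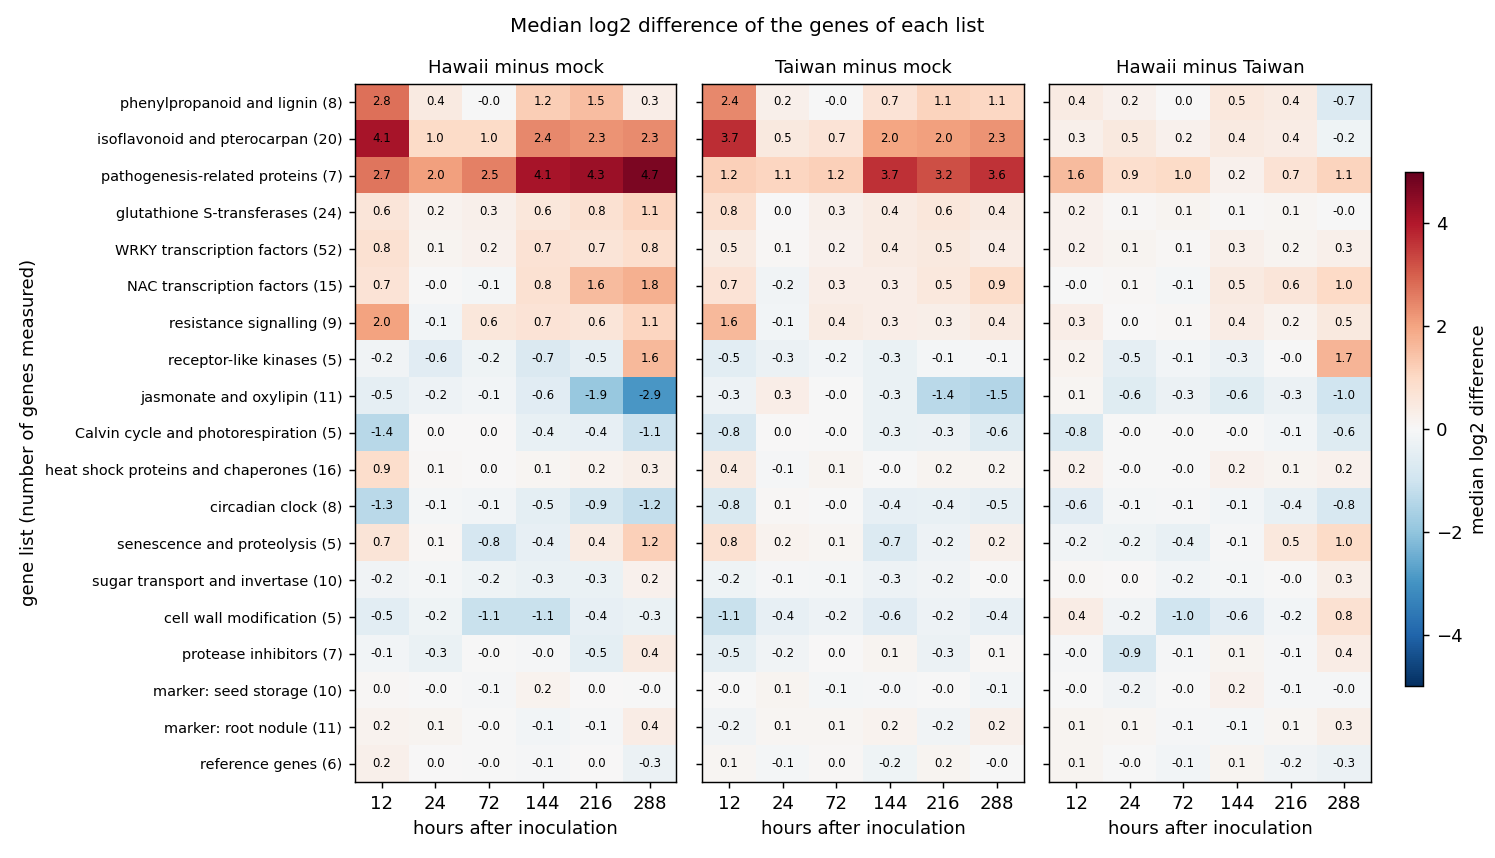
Median log2 difference of the members of 19 gene lists (colour) for each of the 3 contrasts between treatments at 6 times in hours. The isoflavonoid list had medians of 4.11 and 3.68 at 12 h for Hawaii 94-1 and Taiwan 80-2 against mock.

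The isolates were compared with each other at 288 h to ask how the late states of the leaf differed. EN1 was higher in Hawaii 94-1 than in Taiwan 80-2 leaves by 5.43 ± 0.49 (SE, n = 3 per group; adjusted p = 5.48e-11), with a mean log2 signal of 6.76 ± 0.37 in mock, 6.6 ± 0.60 in Taiwan 80-2 and 12.03 ± 0.90 in Hawaii 94-1 leaves (SD). PRX4 was higher by 5.56 ± 1.11 (adjusted p = 0.000179), and AMT1.3 was lower with a difference of −5.86 ± 0.68 (adjusted p = 1.54e-08). CYSP1 and CYSP2 were higher by 4.74 ± 0.41 and 4.51 ± 0.55, and 3 senescence genes were higher in all (3 adjusted over the list alone, 5 over all probe sets with the arrays centred; camera adjusted p = 0.00497, and 0.311 with an estimated correlation). The lipoxygenases LOXB1 and LOX9 had differences of −4.79 ± 0.49 and −3.69 ± 0.60, and 5 jasmonate genes were lower (5 adjusted over the list alone). All 3 vegetative storage genes were lower (3 adjusted over the list alone), VLXB with −3.64 ± 0.44 and VLXC with −2.59 ± 0.61. LOXB1 had a mean log2 signal of 14.30 ± 0.10 in mock, 12.83 ± 0.85 in Taiwan 80-2 and 8.04 ± 1.87 in Hawaii 94-1 leaves (SD). All 4 light reaction genes were lower, PSAD with −1.72 ± 0.19 and ATPC with −1.59 ± 0.22, as were 4 Calvin cycle genes (4 adjusted over the list alone, 2 over all probe sets with the arrays centred; camera adjusted p = 0.0184, and 0.452 with an estimated correlation), FBP with −2.51 ± 0.26 and RCA14 with −0.54 ± 0.14. CHLH had a difference of −2.57 ± 0.31, COL2A of −2.90 ± 0.44 and MYB173 of −1.49 ± 0.38, among 4 lower clock genes (4 adjusted over the list alone, 2 over all probe sets with the arrays centred). APX2 was called in both directions, with differences of 6.67 ± 2.26 and −6.78 ± 2.12 on the same 2 probe sets (adjusted p = 0.0239 and 0.0143), with all arrays of each of these groups at the same level.

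At 288 h 167 of 975 named genes were higher and 182 lower in Hawaii 94-1 than in Taiwan 80-2 leaves. The share of higher WRKY factors was near this base. Of the WRKY factors 9 were higher and 2 lower (8 and 2 adjusted over the list alone, and over all probe sets 7 and 4 with the values as deposited and 14 and 2 with the arrays centred), WRKY8 by 3.07 ± 0.40 and WRKY41 by 1.96 ± 0.31. Of the NAC factors 6 were higher and 1 lower (7 and 1 adjusted over the list alone; over all probe sets 7 higher alone with the values as deposited and 8 higher alone with the arrays centred), NAC51 by 1.88 ± 0.35 and NAC4 by 1.87 ± 0.43. RLK3 was higher by 3.82 ± 0.39 and RLK2 by 1.71 ± 0.24, among 3 receptor-like kinases (3 higher and 1 lower adjusted over the list alone), and ERF5 by 3.11 ± 0.42. SWEET29 and SWEET17, sugar exporters, were higher by 2.69 ± 0.43 and 1.61 ± 0.47, the trypsin inhibitor KTI-2 by 3.51 ± 0.96 and CYSTATIN by 0.56 ± 0.15. XTH1 was higher by 1.00 ± 0.39, but was not called with the values as deposited. Of the pathogenesis-related proteins 1 was higher, and 4 with the arrays centred. Of the isoflavonoid genes 2 were higher, CHR3 by 2.37 ± 0.34 and CHR4 by 0.96 ± 0.28, and 2 lower (2 and 2 adjusted over the list alone, and 3 and 1 over all probe sets with the arrays centred). 4CL2 had a difference of −0.97 ± 0.37, and 1 phenylpropanoid gene was lower (4 adjusted over the list alone). Of the glutathione S-transferases 4 were higher and 3 lower (4 and 3 adjusted over the list alone), GSTU9 by 1.64 ± 0.32 and GSTU30 with −1.98 ± 0.41. PAD4 was higher by 1.15 ± 0.31, and the membrane protein RIN4c had −0.89 ± 0.20 and the NBS-LRR protein KR3 −0.94 ± 0.25. All 4 ribosomal protein genes were lower, RPS6 with −1.10 ± 0.28 and RPS13 with −0.71 ± 0.22, but limma called 0 of them with the arrays centred. Of the heat shock genes 3 were higher and 2 lower (3 and 3 adjusted over the list alone; over all probe sets 3 lower alone with the values as deposited, and 5 and 2 with the arrays centred), HSP90-1 with −0.93 ± 0.26 and HSP23.9 with −1.67 ± 0.49. With the arrays centred 4CL2, RCA14 and HSP90-1 were not called.

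Limma called 9895 probe sets between the isolates at 288 h, 4639 higher and 5256 lower in Hawaii 94-1 leaves, and 5898 without Hawaii replicate 3. Of the calls 46.9% were higher, against 33.6% with the values as deposited (3780 of 11245) and 62.3% with each array centred on its median (6519 of 10471). The median of all probe sets was −0.03, and −0.17 and 0.15 under those scalings.

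Whether the response changed over time was asked with limma's F-test of each difference against that at 12 h. HIDH, CHS1 and STP1 had the smallest adjusted p among named genes for Hawaii 94-1 against mock (5.24e-11, 2.21e-10 and 3.47e-10), where HIDH and STP1 were read on probe sets other than their brightest. HIDH, CHS1 and SCA1 had the smallest for Taiwan 80-2 against mock (1.04e-09, 5.36e-09 and 6.26e-08). BCH3, CYSP1 and EN1 had the smallest for Hawaii 94-1 against Taiwan 80-2 (3.11e-09, 3.45e-08 and 1.21e-07). Limma called 12760, 2151 and 3766 probe sets in these 3 tests. Without replicate 1 of every group the counts were 6746, 950 and 841, without replicate 3 they were 5328, 520 and 325, and without replicate 2 the count for Taiwan 80-2 against mock was 905. In simulated data the tests recovered 50%, 63.6% and 62.1% of 4-fold changes, in the same order.

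The responses to the 2 isolates were compared over all tested probe sets. At 12 h 2473 probe sets rose in both, against 331 for independent lists, 2273 fell in both, against 429, and limma called 0 in opposite directions out of 10609 and 5211 calls. The covariance of the 2 differences across probe sets, which are not independent replicates, was 0.682 at 12 h, against 0.065 in 10 simulations of arrays that share only the mock group. It was 0.147 at 24 h and 0.108 at 72 h, against 0.0644 at each, and the share of probe sets with the same sign at 72 h was 67.6%, against 66.6%. It was 0.403 at 144 h, 0.404 at 216 h and 0.634 at 288 h, against 0.0641, 0.0638 and 0.0641. At 288 h 1591 probe sets rose in both and 1418 fell in both, and 40 were called in opposite directions. The 3 mock arrays of a time served both contrasts and could not be parted into independent groups.

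Markers of other organs and reference genes were read in the same contrasts. Of 10 seed storage genes, 1 rose and 2 fell at 288 h in Hawaii 94-1 leaves (1 and 2 adjusted over the list alone), LEA-2 by −0.74 ± 0.20 and GY7 by −1.0 ± 0.35, and LEA-2 fell by 0.58 ± 0.20 at 12 h in Taiwan 80-2 leaves (SE, n = 3 per group). The rise at 288 h was not called with the values as deposited. With the arrays centred neither fall at 288 h was called, and the fall at 12 h was called under neither other scaling. Between the isolates at 288 h LEA5 was higher by 1.53 ± 0.39 and LEA-2 had a difference of −0.62 ± 0.20, which was called under neither other scaling. Of 11 root nodule genes 1 rose at 216 h, ENOD40B by 1.62 ± 0.39 in Hawaii 94-1 leaves, and 1 rose there at 288 h (3 with the arrays centred). At 288 h 4 were higher in Hawaii 94-1 than in Taiwan 80-2 leaves (4 adjusted over the list alone, and 2 over all probe sets with the values as deposited), N-26 by 0.83 ± 0.26 and NOD33 by 2.81 ± 1.02 among them. The base was 167 of 975 genes. MYB60, the guard cell marker, was not called in any contrast, but was called lower in Hawaii 94-1 than in mock leaves at 216 h under both other scalings and at 288 h with the values as deposited. Among 6 reference genes TUBB2, a tubulin, rose by 0.90 ± 0.23 at 12 h in Hawaii 94-1 leaves (1 adjusted over the list alone). At 288 h the elongation factor TEFS1 and TUBB2 differed between the isolates by −0.60 ± 0.12 and −0.79 ± 0.23, neither called with the arrays centred, where 1 reference gene was higher instead. ZIP43, the only iron and zinc transport gene, rose by 0.96 ± 0.31 at 12 h in Hawaii 94-1 leaves.

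**Figure D4:**
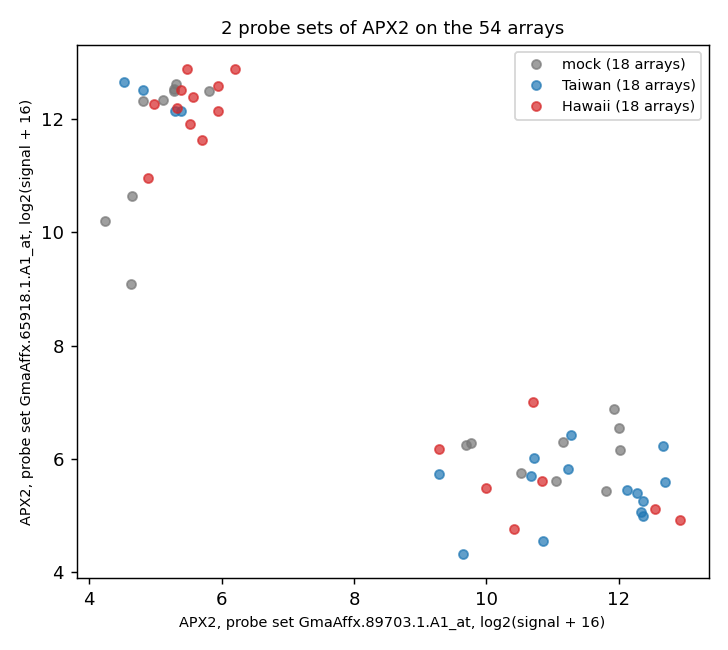
Log2(signal + 16) of 2 APX2 probe sets (axes) on 54 arrays (points), 18 per treatment. Exactly 1 of the probe sets was high on each of the 54 arrays.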

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

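The test of scaling at 288 h, the sorting of splits by replicate number, the draws that keep the replicate numbers and all tests of the switching probe sets were chosen after those results were seen; the other tests of this part were written down before.

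The isolates differed from each other in the number of probe sets called when the difference itself was tested, which is what put these results here: 697 at 12 h, 1 at 24 h, 16 at 144 h, 217 at 216 h and 9895 at 288 h. With 3 arrays against 3, 10 splits are too few for a share under 0.05. The highest counts of the other splits were 1218, 3, 1, 26 and 1321 in that order, and 2, 2, 1, 1 and 1 of the 10 splits gave as many calls as the real one, the real one included. At 72 h the real count was 0, limma found 2872 at an unadjusted p under 0.05, and all 10 splits gave as many, as any split must, with 21 as the highest other count. A split that calls many more than the real one points to a structure of the samples. Same-numbered arrays deviated together in 4 comparisons. Among the other splits that parted all pairs the highest count with limma was 0 in each of these, and among those that parted 1 pair it was 3 and 1 for the isolates at 24 h and 144 h, 9 for Hawaii 94-1 against mock at 216 h and 0 for Taiwan 80-2 against mock at 288 h. For the isolates at 12 h every same-numbered pair deviated apart, with correlations from −0.525 to −0.17, and the split with 1218 calls parted all pairs.

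The change of each difference over time was tested too, and 12760 probe sets for Hawaii 94-1 against mock, 2151 for Taiwan 80-2 against mock and 3766 for Hawaii 94-1 against Taiwan 80-2 are listed here because the effect differed between times. Of 100 draws, 3, 2 and 7 gave as many calls, the real labels included, with 16393, 2261 and 6022 as the highest other counts. By these draws chance was excluded for the first and second and was not excluded for the third. With labels exchanged only between same-numbered arrays, 4, 10 and 10 of 100 draws gave as many, with 15437, 4169 and 5177 as the highest other counts, so chance was excluded in both ways for the first alone and stays open for the second. A draw that exchanges all labels of a time turns the sign of that difference and enlarges the interaction, so a high count in single draws is built into this test. For mock leaves over time 1 of 100 draws reached the real count of 20490, the highest other count was 9143, and chance was excluded; with labels exchanged only within replicate numbers 1 of 100 reached it and the highest other count was 14030.

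For the contrasts with mock the 10 splits are again too few for a share under 0.05. For Hawaii 94-1 the real counts were 10609, 287, 421, 4285, 6120 and 14419 from 12 to 288 h, the highest other counts were 2525, 42, 257, 4, 9 and 1473, and 1 split reached the real count at each time. For Taiwan 80-2 the real counts were 5211, 10, 9, 1537, 1443 and 3679, the highest other counts 1051, 68, 100, 249, 4 and 0, and 1, 2, 5, 1, 1 and 1 splits reached the real count. At 24 h and 72 h other splits called several times the real count of Taiwan 80-2, which points to a structure of the samples, and single arrays moved these counts, as given in the report.

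The first pattern weighed was the large response to Hawaii 94-1 at 12 h followed by few calls at 24 h and 72 h. An odd array at 12 h is argued against by a lowest count of 8888 of 10609 with 1 of the 6 arrays left out. Leaving out 1 array took the low counts up to 475 at 24 h (mock replicate 2) and 1326 at 72 h (mock replicate 1). Both stayed under the 12 h count. RNA quality as read by GAPDH is argued against as the whole cause by 10359 calls with the GAPDH covariate. A lasting response hidden by the spread at 24 h is argued against, since over the probe sets called at 12 h the slope of the 24 h difference on the 12 h difference was 0.0988. The slope was not redone without mock replicate 2. G4DT and OLPa were at 9.80 and 8.96 there, against at most 6.36 and 6.01 on the others. A response of the leaf that is brief may account for the pattern, but 12 h also differs from the other times in time of day, which stays open.

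The second pattern was the distance of the Hawaii 94-1 arrays from mock at 288 h. Scaling as the whole cause is argued against, since the lower count under the other 2 scalings was 14700, although the share of higher calls moved with the scaling. RNA quality as read by GAPDH is argued against as the whole cause by 14744 calls with the GAPDH covariate. An odd array is argued against by a lowest count of 11543 with 1 of the 6 arrays left out. A late state of the resistant leaf may account for the pattern, as a hypothesis found on the same arrays and not tested. Tissue death, leaf age and the amount of fungus were not measured.

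The third pattern was a set of 76 probe sets that switched between a low and a high level within groups, chosen by limits set after the values were seen, among them that at least 4 groups held arrays of both states. On the 2 APX2 probe sets the low arrays ranged from 4.24 to 6.20 and 4.32 to 7.0 and the high arrays from 9.28 to 12.9 and 9.08 to 12.9, and exactly 1 of them was high on 54 of 54 arrays (30 and 24), which is consistent with 2 alleles and with a genetic difference between plants of the line. Inoculation or time as the whole cause is argued against for these 2, which the naming rule had picked without that limit, since 10 of the 18 groups held both states, and so the calls of APX2 at 288 h may come from which material was sampled. The same argument holds for 4 others that split all 54 arrays as APX2 did. The other 70 stay open, as the choice fixed at least 4 groups. Without that limit 455 of 560 had both states in at most 2 groups. Probe sets chosen on 3 times had both states in a median of 0 of the 9 groups of other times (373 chosen up to 72 h). For 150 chosen from 144 h it was 3. Whether 1 linked chromosome segment holds these probe sets stays open: the 3 located genes that split the arrays as APX2 did on 50 or more arrays lay on 2 chromosomes (APX2 and LOC100305550 on 12, LOC100499730 on 4). LOC100305550 and LOC100499730 each matched on 50 arrays. The first form of this test excluded a single segment, and the minimum of 6 located genes was set after the value was known.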

How the results depend on the processing

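Of the tests of this part, those stated above as added later were chosen after the data were seen, and the others were planned.

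Counts of calls kept within 1.5 times their value with the values as deposited, with limma's trend and robust settings and with no filter, in all 22 contrasts and F-tests. With each array centred 3 of 22 moved: Hawaii 94-1 against Taiwan 80-2 to 399 at 12 h and 7 at 144 h, and Hawaii 94-1 against mock to 263 at 72 h. With log2(value + 1) 4 of 22 moved: Taiwan 80-2 against mock at 24 h to 17, and the isolates against each other to 0 at 24 h (limma, with 910 at an unadjusted p under 0.05), 3 at 144 h and 126 at 216 h. With the GAPDH covariate the count between the isolates at 144 h moved to 9. The cause was not tested in these cases.

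With only the arrays compared, 14 of 22 moved, with fewer residual degrees of freedom by construction. Hawaii 94-1 against mock went to 6478, 175, 42 and 2843 at 12, 24, 72 and 144 h. Taiwan 80-2 against mock went to 2208, 0, 0, 641 and 681 from 12 to 216 h, with 2107 and 1216 at an unadjusted p under 0.05 for the counts of 0. The isolates against each other went to 0, 0, 0, 1 and 6554 at 12, 24, 144, 216 and 288 h, with 4588, 2328 and 1958 at an unadjusted p under 0.05 by limma for the counts of 0.

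With mock replicate 1, Taiwan replicate 3 and Hawaii replicate 1 at 72 h left out, arrays picked for standing apart, the 72 h counts were 1401 for Hawaii 94-1 against mock, 97 for Taiwan 80-2 against mock and 494 between the isolates. Without 12 h the F-test for Taiwan 80-2 against mock called 845. The cause was not tested.

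The replicate numbers met the bar for pairing in 4 of 18 comparisons: the isolates at 24 h and 144 h, Hawaii 94-1 against mock at 216 h and Taiwan 80-2 against mock at 288 h. Over 54 pairs the correlations ranged from −0.525 to 0.426, with a median of 0.124 and 28 over 0.1. In 35 of 54 pairs the array of the first group correlated best with the same number in the other group, against 18 for shuffled numbers (1-sided permutation test, p = 3e-05). What the numbers share is not given in the labels. With the number within each time as a block the count between the isolates at 24 h moved to 5 and the other 3 counts kept within 1.5 times. With the replicate block over all arrays Taiwan 80-2 against mock went to 17 at 24 h and 14 at 72 h, and the isolates against each other to 4 and 7; the other 18 counts kept within 1.5 times.

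With 1 array left out, the lowest and highest counts from 12 to 288 h were as follows. For Hawaii 94-1 against mock they were 8888 to 10150, 50 to 475, 72 to 1326, 2186 to 4618, 3842 to 5490 and 11543 to 14972. For Taiwan 80-2 against mock they were 3292 to 5408, 0 to 108, 0 to 126, 473 to 1846, 596 to 1581 and 2317 to 2643. Between the isolates they were 256 to 631, 0 to 3, 0 to 317, 0 to 37, 39 to 320 and 5898 to 11534. With 1 replicate number left out of every group, the F-tests called 5328 to 10485 for Hawaii 94-1 against mock, 520 to 950 for Taiwan 80-2 against mock, 325 to 3495 between the isolates and 12456 to 16803 for mock over time.

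Of 195 calls of named genes none was reversed, which only a new scaling, log2(value + 1) or the covariate could do. With only the arrays compared 59 were lost, with the arrays centred 18, with log2(value + 1) 14, with the GAPDH covariate 9, with the values as deposited 6, with trend and robust settings 3, with no filter 3 and with the replicate block 2. Of 540 counts of list members, 103 moved with only the arrays compared, 36 with centring and 27 with each of log2(value + 1) and the covariate. Over the gene lists fixed beforehand and all contrasts, camera made 93 calls with the preset correlation, 116 against all tested probe sets and 0 with an estimated correlation.

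In simulated data 19.4% of 2-fold changes were recovered for Hawaii 94-1 against Taiwan 80-2 at 12 h, 16.7% on probe sets with a mean signal below the median and 24% on the others. For Taiwan 80-2 against mock at 144 h 40.3% were recovered, 33.3% and 48.4%. Of 4-fold changes 94.7% and 92.9% were recovered in the first, and 79.3% and 89.2% in the second.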

Other observations

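The families below and the test of genes that change again late were chosen after the results were seen.

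At 288 h 265 of 975 named genes rose and 246 fell in Hawaii 94-1 leaves, as a base for the families with a shared symbol stem below. In that contrast camera placed none of them above or below the other named genes (smallest adjusted p = 0.139, and 0.694 with an estimated correlation). Of 9 aldehyde dehydrogenases, which oxidise reactive aldehydes, 6 rose and 2 fell against mock, with a median log2 difference of 1.14, and 5 were higher and 1 lower than in Taiwan 80-2 leaves (5 higher alone with each array centred). ALDH3H1 rose by 5.20 ± 0.48 (SE, n = 3 per group; limma adjusted p = 2.1e-11). Of 14 PIP aquaporins, which are plasma membrane water channels, 7 fell against mock (4 with each array centred) and 8 were lower than in Taiwan 80-2 leaves (camera adjusted p = 0.0361 between the isolates, and 0.694 with an estimated correlation). In Taiwan 80-2 leaves 2 aquaporins rose and 1 fell, PIP2-9 rising by 1.59 ± 0.41; 1 rose and 1 fell under each other scaling. Of 20 cytochrome P450 genes, 6 rose and 9 fell against mock, and 3 were higher and 11 lower than in Taiwan 80-2 leaves, with a median of −1.25. CYP82A3 rose by 5.68 ± 0.57 at 12 h in Hawaii 94-1 leaves and by 5.44 ± 0.57 in Taiwan 80-2 leaves.

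Of 19 PM genes, named for seed maturation, 6 rose and 1 fell at 288 h in Hawaii 94-1 leaves, PM1 by 2.63 ± 0.59, and 5 were higher and 1 lower than in Taiwan 80-2 leaves. Of 56 BZIP transcription factors, 15 rose and 13 fell against mock (23 and 11 with each array centred), and 12 were higher and 6 lower than in Taiwan 80-2 leaves. Of 60 MYB factors, 11 rose and 18 fell. Of 11 cyclophilins, 2 rose and 6 fell, and 5 were lower than in Taiwan 80-2 leaves. Of 9 PHR genes, 6 fell at 12 h in Hawaii 94-1 leaves and 3 in Taiwan 80-2 leaves (1 with the values as deposited and 2 with each array centred in the latter). Of 15 GASA peptides 4 fell at 288 h in Hawaii 94-1 leaves while the median difference was 0.32, and of 8 FAD desaturases 2 fell. In these contrasts the balance of rises and falls of each family kept its direction under both other scalings, apart from the aquaporins in Taiwan 80-2 leaves.

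Probe sets that rose at 12 h may belong to a set of response genes that rises again at other times. Of the probe sets that rose in Hawaii 94-1 leaves against mock, 4658 at 12 h and 2986 at 216 h, 1802 rose at both times, against 382 for independent lists, a ratio of 4.72. The ratio of 12 h with 24, 72, 144 and 288 h was 4.93, 5.3, 4.95 and 2.84, so a raised ratio is not particular to late times. The highest ratio possible falls as a list grows, so ratios of lists of unlike size cannot be ranked. The number of the 4658 probe sets that rose again was larger at late times. It was 142, 194, 1577 and 2416 at 24, 72, 144 and 288 h, when 225, 286, 2489 and 6651 rose in all. For falls it was 0.789, 0.816, 3.05, 3.55 and 2.69 with 24 to 288 h. The 2 times have different mock arrays, so shared controls do not account for the overlap. The counts at both times had been seen before, and probe sets with a small spread are called more readily at any time, which was not removed.

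The arrays at 72 h differed within groups in 5 genes picked after their values were seen, which stand for no class of genes. GASA9 had log2 signals of 7.39, 11.1 and 11.9 in mock replicates 1, 2 and 3, 10.6, 9.97 and 6.76 in Taiwan 80-2 and 7.43, 10.4 and 9.72 in Hawaii 94-1 leaves. EXP4 had 8.74, 11.7 and 12.3 in mock, 10.8, 10.9 and 9.94 in Taiwan 80-2 and 9.15, 10.8 and 11.6 in Hawaii 94-1 leaves. PIP1-6 had 8.93, 11.6 and 12 in mock, 11.2, 10.3 and 8.27 in Taiwan 80-2 and 8.14, 8.91 and 10.1 in Hawaii 94-1 leaves. GA2OX6 had 8.87, 5.71 and 6.16 in mock, 6.27, 5.99 and 9.15 in Taiwan 80-2 and 8.83, 5.26 and 5.97 in Hawaii 94-1 leaves. NAC34 had 9.97, 8.40 and 7.84 in mock, 8.80, 8.49 and 10.3 in Taiwan 80-2 and 10.3, 8.24 and 8.77 in Hawaii 94-1 leaves.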
